A study of Rattus norvegicus with 9 samples.

How the data were processed

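Bulk RNA was sequenced from rat femurs taken at day 7 in 3 groups of 3 libraries: sham surgery (Sham), injury of the distal femoral growth plate (GPI), and the same injury treated with a hydrogel that the labels call GMTT. The series title names its parts as GelMA (methacrylated gelatin), TPGS (a vitamin E derivative) and tea polyphenols. Per the labels' protocols, RNA was extracted with TRIzol, selected by poly(A), and made into strand-specific libraries by the dUTP method for paired-end sequencing. The authors deposited whole-number read counts per gene and, separately, FPKM values per gene. The genome build was mRatBN7.2 per the submitters' processing notes. The aligner, the counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here, so genes of near-identical families (alpha-defensins such as Defa5 and Np4, the lysozymes Lyz2 and Lyc2, ribosomal protein copies, major histocompatibility genes) and genes overlapping on opposite strands are uncertain. The labels place 3 rats in each group, 1 library each by their numbering. They do not say whether tissue was pooled, so p-values measure the spread between these libraries.

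The count table held 31125 gene rows, of which 563 were gene models without a symbol, and 8652 had no count in any library. Totals ran from 15927429 to 19715997 counts per library. The deposited FPKM equalled count over gene length over 1 constant per library, to a relative deviation of 5.11e-15. That constant was 0.604 of the library total in GPI, 1.32 in Sham and 1.30 in GMTT (means of 3), and it matched a median-of-ratios size factor, so FPKM already carries a scaling between libraries and is not relative to the raw total.

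Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust dispersions, 2-sided) in R 4.3.3, with all 9 libraries in 1 model of 3 groups, TMM scaling and the default low-count filter (minimum count 10), which left 15936 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Normalised CPM below are TMM-scaled, fold changes are log2 with the standard error (SE), and group values are mean ± SD of 3 libraries. TMM factors averaged 1.28 in Sham, 0.602 in GPI and 1.29 in GMTT. The 3 contrasts were GPI against Sham, GMTT against GPI and GMTT against Sham. Counting intervals have a confidence level of 95%, and a group with no count was given a floor of 3 counts over the group; both cover counting error only.

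The 30 gene lists, fixed before the data were examined like the groups and main tests, were matched by symbol (the gene with the highest mean count where a symbol recurred) and tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over the 30 lists of a contrast. They cover pyroptosis, other cell death, inflammatory and interferon genes, cartilage, growth plate signalling, matrix degradation, bone cells, repair matrix, vessels, tendon and synovium, antioxidant genes, glycolysis, respiration, ribosomal proteins, proliferation, immediate early genes, growth factor signalling, blood lineages, skeletal muscle, fat and nerve. Some genes sit in more than 1 list, such as Spp1 and Mmp13. Genes named were set by a rule: the 6 genes of the NLRP3 and caspase-1 axis; 8 cartilage and antioxidant genes; the 5 highest and 5 lowest fold changes among called genes with a mean log2 CPM of at least 3, no overlap between groups and a proper symbol; the 2 members with the smallest p of the 8 lists with the smallest camera p; and up to 4 members of a list by p. Not every gene the rule takes is reported here. Names outside this rule are marked as chosen after their values were seen.

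Alternatives were median-of-ratios scaling, library sizes only, DESeq2 1.42.0, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, fits of 6 libraries, a replicate block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold minimum, and leaving out each library in turn. After seeing the data, a fit without mitochondrially encoded, skeletal muscle and erythroid list genes and a scaling of the axis genes to 16 leukocyte reference genes were added. On simulated counts with 50 changed genes per fold size, the test of GPI against Sham over 15223 genes recovered 98% of 4-fold, 98% of 2-fold, 82% of 1.5-fold and 62% of 1.25-fold changes and called 0.0666% of unchanged genes. For GMTT against GPI, over 14277 genes, these were 100%, 96%, 84% and 52% with 0.0497%, and for GMTT against Sham, over 15208 genes, 100%, 98%, 84% and 50% with 0.0733%. All simulated libraries shared the same profile apart from the changed genes, which went up and down in equal number. The TMM assumption was thus met by construction, so these rates do not cover contrasts in which most genes differ. Figures were drawn with matplotlib 3.10.9.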

Results

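The 9 femur libraries held between 15927429 and 19715997 counts each. Correlations across genes were 0.991 to 0.995 within groups, 0.614 to 0.617 between GPI and Sham, 0.714 to 0.716 between GMTT and GPI and 0.955 to 0.957 between GMTT and Sham. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 1.99 to 5.15, and each library was kept as 1 sample. The median biological coefficient of variation was 5.09%.

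The groups differed widely in the share of counts held by genes of single tissues. Skeletal muscle genes took 0.363% ± 0.0112 of the counts in Sham, 17.2% ± 0.156 in GPI and 3.45% ± 0.121 in GMTT, and mitochondrially encoded genes took 3.83% ± 0.185, 26.2% ± 0.755 and 6.05% ± 0.343 (SD, n = 3). Erythroid genes took 8.95% ± 0.487 in Sham, 0.257% ± 0.00320 in GPI and 4.85% ± 0.207 in GMTT. Genes of neutrophils and their marrow precursors took 1.47% ± 0.0523 in Sham, 0.000989% ± 0.000108 in GPI and 1.75% ± 0.0419 in GMTT. These differences stand beside every gene group compared below. The labels describe femurs in every group and do not say how much muscle or marrow was kept, so all 3 contrasts compare the tissue as taken.

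**Figure D1:**
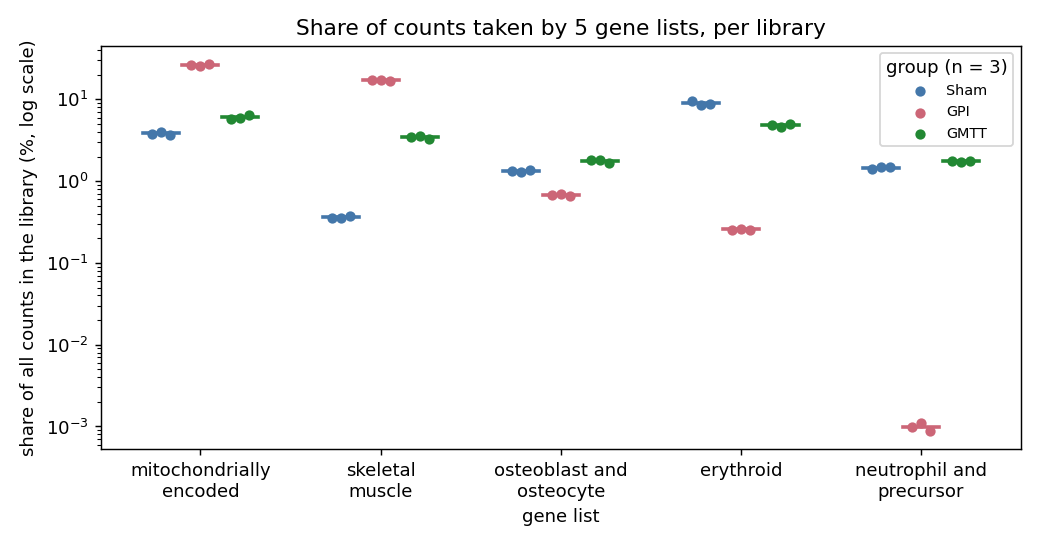
Share of all counts (%, log axis) held by 5 gene lists in each library; points are libraries and bars are group means of 3. GPI libraries lie near 17.2% for skeletal muscle against 0.363% in Sham, and near 0.000989% for the neutrophil list against 1.47% in Sham.

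The first comparison, GPI against Sham, addresses the effect of growth plate injury at day 7. Muscle genes rose and blood-forming genes fell in GPI. Abra, an actin-binding regulator of striated muscle, rose from 1.45 ± 0.241 to 914 ± 20.3 normalised CPM (SD, n = 3), a log2 fold change of 9.30 (SE 0.08). Xirp1, Myf6, Cntfr and Pdk4 rose by 9.12, 8.51, 8.24 and 8.16 (log2). The erythroid urea transporter gene Slc14a1 and Ifitm6 had no count in GPI and were at least 1257-fold and 951.7-fold lower than in Sham. Ermap and Rhag, both of red cells, had 2 counts each over the GPI libraries against 22952 and 22591 in Sham, ratios of 5994 (counting interval 1659 to 49500) and 5900 (1633 to 48720). Prg3, an eosinophil granule gene, had 3 against 29874 (ratio 5201, 1780 to 25220). In all, 14049 of 15936 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6387 higher and 7662 lower. With library sizes only the split was 3521 higher and 11210 lower, and the median of all genes moved from -0.19 to -1.28 (log2), so directions below are relative to the TMM scale.

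The series title names the NLRP3 and caspase-1 route of pyroptosis, in which the NLRP3 sensor and the adaptor ASC (Pycard) activate caspase-1, which cleaves gasdermin D (Gsdmd) and the precursors of the cytokines IL-1 beta and IL-18. All 6 genes of this axis were lower in GPI than in Sham on the TMM scale. Nlrp3 (ENSRNOG00000003170, mRatBN7.2 chromosome 10, 44328566 to 44352811) fell from 19.5 ± 0.971 to 0.498 ± 0.0874 normalised CPM, a log2 fold change of -5.27 (SE 0.19). Casp1 (ENSRNOG00000007372, chromosome 8, 2587831 to 2597383) fell from 32.6 ± 1.03 to 4.90 ± 0.811, a change of -2.74 (SE 0.11). Pycard (ENSRNOG00000019675, chromosome 1, 182601174 to 182602955), Gsdmd (ENSRNOG00000007728, chromosome 7, 107542083 to 107547055), Il1b (ENSRNOG00000004649, chromosome 3, 116577010 to 116583415) and Il18 (ENSRNOG00000009848, chromosome 8, 50906960 to 50932887) changed by -4.11, -1.57, -4.37 and -2.18; all 6 are protein-coding. Their adjusted p ranged from 2.63e-23 (Pycard) to 4.58e-07 (Il18) in edgeR's quasi-likelihood test. Scaled instead to 16 leukocyte genes, whose median fell by 5.34, the differences turned positive, from 0.20 for Nlrp3 (adjusted p = 0.593, same test) to 3.93 for Gsdmd. This scaling was chosen after the axis values were seen and shifts all genes by nearly the same amount, so the sign says only whether a gene fell less than the leukocyte genes did on average. The leukocyte genes themselves changed by -7.18 to -1.60, a range that held every axis gene except Gsdmd. Tests on this scale take no account of that range. Of the 17 members of the NLRP3 inflammasome and pyroptosis list, 14 fell and 3 rose, with the same counts adjusted over the list alone; Mefv fell by 6.29 and Txnip, which encodes a thioredoxin inhibitor, rose by 1.58. The camera call of this list (adjusted p = 0.0093) was lost at adjusted p = 0.109 with an estimated correlation and at 0.1 with library sizes only.

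**Figure D2:**
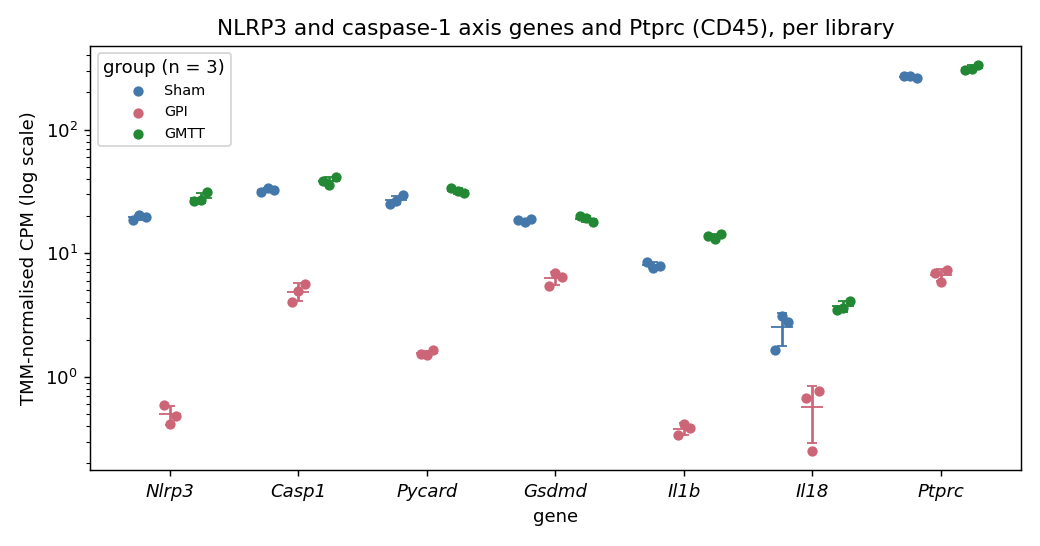
Normalised CPM (log axis) of the 6 NLRP3 and caspase-1 axis genes and of Ptprc, which encodes the leukocyte antigen CD45, in each library; points are libraries, and horizontal marks with error bars are mean ± SD of 3. Nlrp3 lies at 19.5 in Sham, 0.498 in GPI and 28.1 in GMTT. Scaling to leukocyte genes shifts all genes by nearly the same amount, which turns the GPI to Sham differences of the axis genes positive, Nlrp3 not being called (log2 0.20, adjusted p = 0.593).

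Cartilage genes went both ways in GPI. Col2a1, the main cartilage collagen, fell from 13.9 ± 0.955 to 3.71 ± 0.221 normalised CPM (log2 -1.90, SE 0.13), while Col10a1, the collagen of hypertrophic chondrocytes, rose from 1.76 ± 0.506 to 14.5 ± 0.858 (3.05, SE 0.15). The chondrocyte regulator Sox9 rose by 1.40 (SE 0.24), from 1.16 to 3.08 CPM, and was 0.31 higher and not called with library sizes only. The proteoglycan gene Acan was 0.77 higher (SE 0.08), which turned to -0.33 with library sizes only. Ihh was too low to test, with 3 counts in GPI and 10 in Sham. Of 16 tested cartilage matrix genes 8 rose and 5 fell, and of 17 hypertrophic and growth plate signalling genes 6 rose and 9 fell, with the same counts adjusted over the list alone; neither list was called by camera (adjusted p = 0.335 and 0.728; by fry, which does not compare a list with other genes, 0.0178 and 5.27e-07), and the second turned direction with library sizes only. The collagenase gene Mmp13 fell from 321 ± 12.9 to 5.03 ± 1.04 CPM (log2 -6.00, SE 0.09), Spp1 fell by 4.58, and Mef2c, which muscle also expresses, rose by 4.06.

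Bone, marrow and dividing-cell genes fell in GPI, beside the lower erythroid and neutrophil shares. Of 22 osteoblast and osteocyte genes 16 fell and 4 rose, among the lower Mepe (-5.57) and the osteocyte gene Dmp1 (-4.33) (camera adjusted p = 0.00991; adjusted p = 0.0964 with an estimated correlation). Of 17 osteoclast genes 15 fell, including Car2 (-6.96) and Mmp9 (-7.39), and all 23 proliferation genes fell, including Mki67 from 1609 ± 65.9 to 10.2 ± 1.05 CPM (log2 -7.30) and Top2a (-6.13). In the blood lineages, 18 of 19 erythroid, 22 of 22 neutrophil, 19 of 19 monocyte and macrophage, 19 of 19 B lymphocyte, 13 of 13 megakaryocyte and 16 of 17 mast cell, basophil and eosinophil genes fell. Examples were Slc4a1 of red cells (-9.56), Ngp and Np4 of granules (-10.34 and -11.66), Lyz2 of macrophages (-6.58) and Cd79a and Cd79b of the B cell receptor (-9.12 and -9.39). The camera calls of the osteoclast, proliferation and these blood lists held with an estimated correlation (adjusted p 0.0117 to 0.0261). Of 19 T and NK lymphocyte genes 14 fell and 2 rose, among them Cd28 (5.52), while Lck fell (-4.03) and Nkg7 had 3 counts against 4541, a ratio of 790.6 with a counting interval of 270.4 to 3835 (camera adjusted p = 0.012; adjusted p = 0.0648 with an estimated correlation and 0.181 with library sizes only). Of 79 cytosolic ribosomal protein genes 70 fell and 1 rose, the muscle paralogue Rpl3l (4.05), against -2.74 for Rpl3 (list adjusted p = 4.49e-06; adjusted p = 0.282 with an estimated correlation). The counts in this paragraph were the same adjusted over the list alone.

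Muscle, respiration, fat and connective tissue genes rose, beside the higher muscle and mitochondrial shares. All 26 skeletal muscle genes rose, including the myosin genes Myh2, from 97.0 ± 3.04 to 18790 ± 124 CPM (log2 7.60), and Myh4 (6.62), with a list median of 6.31 (camera adjusted p = 1.01e-12; adjusted p = 0.0609 with an estimated correlation). All 23 nuclear oxidative phosphorylation genes, such as Ndufs1 (3.83) and Sdha (3.41), and all 13 mitochondrially encoded genes, such as Mt-nd5 (4.60) and Mt-nd2 (4.19), rose (adjusted p = 1.03e-09 and 1.76e-06; adjusted p = 0.079 and 0.18 with an estimated correlation). The adipocyte list had 16 of 18 genes higher, including Lpl (5.30), the tendon and synovium list 10 of 10, including Thbs4 (4.02), and the fibrous repair list 18 of 22, including Col3a1 (2.56) and Postn (2.28), and these 3 calls held with an estimated correlation (adjusted p = 0.0463, 0.0211 and 0.0172). Of 17 endothelial and vessel genes 15 rose, including Vegfa (4.76), which also sits in the hypoxia and glycolysis list. Of 19 immediate early and heat shock genes 15 rose, including Atf3 (6.51). Camera adjusted p of these 2 lists was 0.000169 and 0.00262 (adjusted p = 0.0689 for each with an estimated correlation). Counts adjusted over the list alone were the same.

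The lists left were not called by camera in GPI against Sham, though fry called them, matrix degradation and antioxidant genes in the direction opposite to camera's. Other regulated cell death had 14 genes lower and 4 higher of 21, inflammatory cytokines and NF-kB targets 14 lower and 2 higher of 19, interferon response 10 higher and 4 lower of 17, matrix degradation 8 each way of 19, and nerve and Schwann cell 9 higher and 3 lower of 12. The NRF2 and antioxidant list had 11 higher and 12 lower of 24: Sod2 rose by 3.06, while Gpx1 fell by 3.00 and Hmox1, heme oxygenase 1, fell by 3.57. Nqo1, a quinone reductase, rose by 1.13 (SE 0.12) and was 0.04 higher and not called with library sizes only. Hypoxia and glycolysis had 12 higher and 8 lower of 20, and BMP, TGF-beta and Wnt signalling 15 higher and 8 lower of 24. Camera adjusted p of these lists ranged from 0.0662 (nerve) to 0.958 (antioxidant), and with library sizes only the nerve and hypoxia lists passed, at 0.00582 and 0.0176. The matrix degradation list had a median of 0.08 and a mean of -0.95 and the antioxidant list a median of -0.20 and a mean of -0.10, while camera put both higher. Counts adjusted over the list alone were the same.

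**Figure D3:**
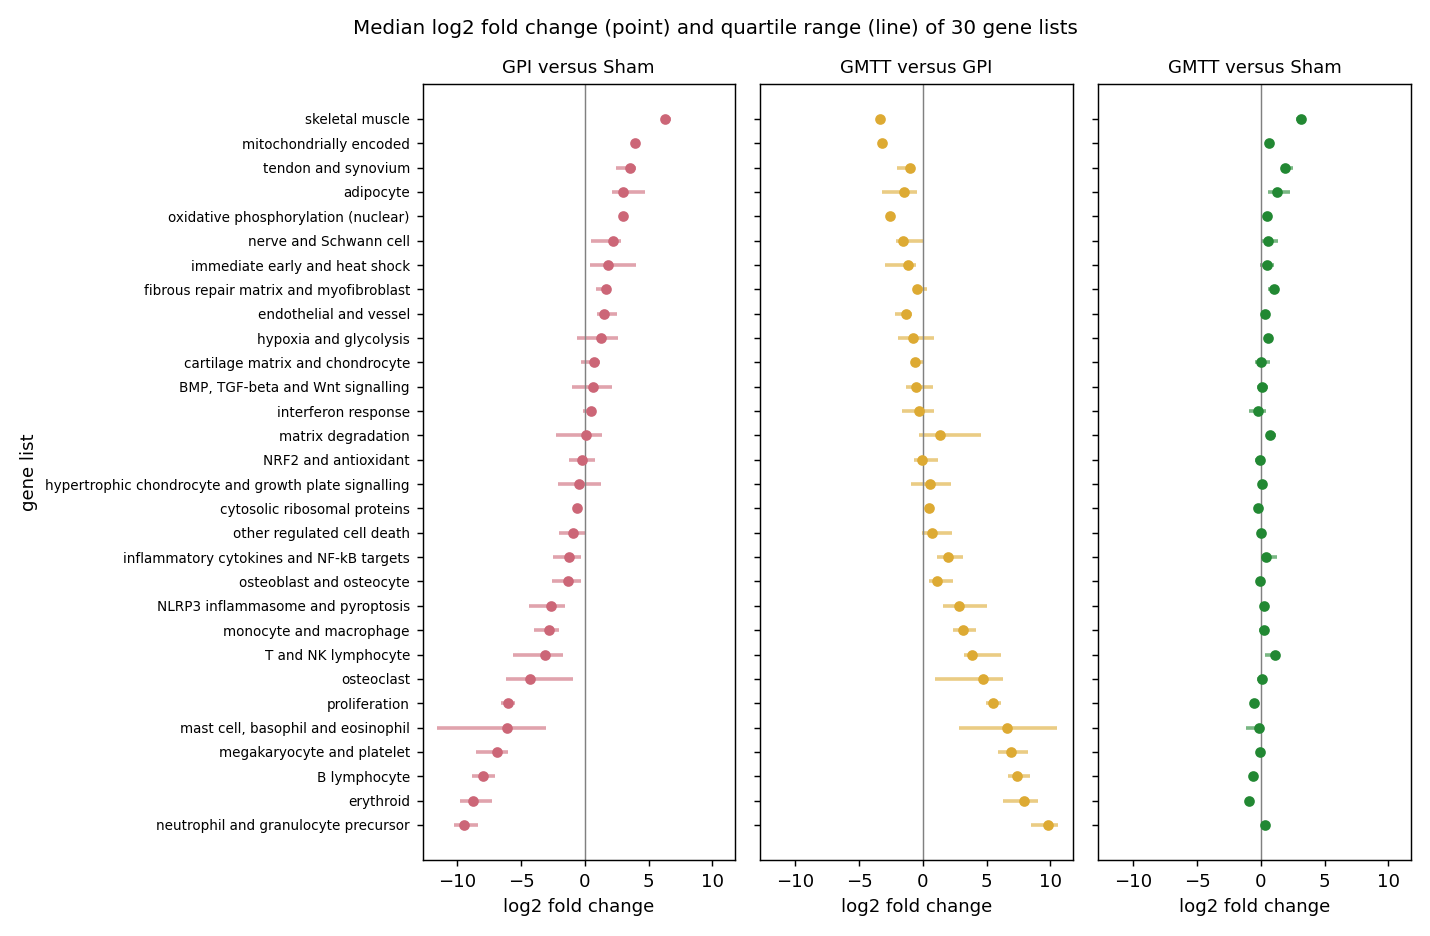
Median log2 fold change (points) and quartile range (lines) of the tested members of 30 gene lists in each contrast, ordered by GPI against Sham. The medians run from -9.49 (neutrophil) to 6.31 (skeletal muscle) in GPI against Sham and from -0.91 (erythroid) to 3.13 (skeletal muscle) in GMTT against Sham; the hypertrophic and fibrous repair lists are among those whose test direction turns with library sizes only.

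The second comparison, GMTT against GPI, addresses the effect of the hydrogel in injured femurs. Blood-lineage genes rose and muscle genes fell in GMTT. Ifitm6 and Slc14a1 were at least 1027-fold and 725.6-fold higher, Mcpt10, a mast cell protease gene, had 18927 counts against 1 (ratio 9356, counting interval 1679 to 369500), Cd177 of neutrophils 21121 against 3 (ratio 3480, 1191 to 16880), and Np4 rose by 11.84 (log2). Abra fell from 914 ± 20.3 to 18.0 ± 0.579 normalised CPM (log2 -5.67, SE 0.06), and Pdk4 (-5.56), Ankrd1 (-5.43), Xirp1 (-5.06) and Cntfr (-4.97) fell too. In all, 13685 genes were called, 7285 higher and 6400 lower, against 11503 higher and 3016 lower with library sizes only.

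All 6 axis genes were higher in GMTT than in GPI, beside the higher neutrophil share. Nlrp3 rose from 0.498 ± 0.0874 to 28.1 ± 2.80 normalised CPM (log2 5.80, SE 0.18), Casp1 by 2.98, Pycard by 4.36, Gsdmd by 1.60, Il1b by 5.15 and Il18 by 2.73. Their adjusted p ranged from 2.88e-24 (Pycard) to 1.37e-09 (Il18) in edgeR's quasi-likelihood test. Scaled to leukocyte genes, whose median rose by 5.56, Casp1, Pycard, Gsdmd, Il1b and Il18 turned to -2.66, -1.28, -4.04, -0.47 (not called) and -2.89, and Nlrp3 was 0.18 (adjusted p = 0.626, same test). The leukocyte genes themselves rose by 1.51 to 7.26, and the TMM values of all 6 axis genes lay within this range. The inflammasome list had 14 genes higher and 3 lower of 17 (camera adjusted p = 0.00306; adjusted p = 0.0803 with an estimated correlation and 0.0578 with library sizes only). The inflammatory list had 18 of 19 higher, including Vcam1 (3.63) and Il1rn (6.67), and its call (adjusted p = 0.00314) held with an estimated correlation but was lost at 0.0837 with library sizes only.

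Col10a1 fell from 14.5 ± 0.858 to 1.33 ± 0.0279 CPM (log2 -3.44, SE 0.16) and Sox9 fell by 1.89 (SE 0.26), while Mmp13 rose by 5.94 to 309 ± 21.8 CPM. Col2a1 was lower still, at -0.64 (SE 0.18), but 0.46 higher with library sizes only. Acan (-0.08, adjusted p = 0.342 in edgeR's quasi-likelihood test) was not called and stood at 1.02 with library sizes only. Nqo1 was -0.25 (SE 0.11), a call lost without any 1 GPI library or GMTT replicate 2, with DESeq2, with no low-count filter, on log2(FPKM + 0.1) and on unfiltered log2(FPKM + 1), and turned to 0.85 with library sizes only, and Hmox1 rose by 2.96. The cartilage list had 4 higher and 9 lower of 16 and the hypertrophic list 9 higher and 6 lower of 17, neither called by camera (adjusted p = 0.289 and 0.646; by fry 0.141 and 8.12e-08).

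Lists of marrow, bone and dividing cells rose, among them 23 of 23 proliferation genes (Mki67 6.74, Top2a 5.83), 22 of 22 neutrophil genes (Ngp 10.65), 18 of 19 erythroid genes (Slc4a1 8.70), 19 of 19 B lymphocyte genes (Cd79a 8.41, Cd79b 8.61), 18 of 19 monocyte genes (Lyz2 6.62, Itgam 6.34), 13 of 13 megakaryocyte genes, 16 of 17 mast cell genes, 17 of 19 T and NK genes and 16 of 17 osteoclast genes. Their camera calls held with an estimated correlation (adjusted p 0.00863 to 0.033), though that of T and NK genes was 0.0594 with library sizes only. All 26 muscle genes fell, including Myh2 (-4.65) and Ryr1 (-4.11), as did all 23 oxidative phosphorylation genes, including Ndufs1 (-3.06) and Uqcrc2 (-2.92), and all 13 mitochondrially encoded genes, including Mt-nd5 (-3.66) and Mt-nd2 (-3.40). No list that fell kept its call: adjusted p with an estimated correlation was 0.0714 for muscle, 0.08 for oxidative phosphorylation, 0.176 for mitochondrially encoded, 0.0803 for endothelial (14 of 17 lower), 0.0875 for tendon and synovium (8 of 10), 0.0714 for immediate early (15 of 19) and 0.0756 for adipocyte genes (15 of 18). The osteoblast list (19 of 22 higher) and the ribosomal list (61 of 79 higher) were called, with adjusted p = 0.0575 and 0.375 with an estimated correlation. The other lists were not called by camera, from adjusted p = 0.0614 (fibrous repair, 16 of 22 lower, but turned upward with library sizes only) to 0.646 (antioxidant and hypertrophic), though nerve genes passed at 0.0315 with library sizes only. The antioxidant list had a median of -0.06 and a mean of 0.11 and was put lower by camera. Counts adjusted over the list alone were the same in this contrast.

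The third comparison, GMTT against Sham, addresses what still differed from sham surgery in the tissue as taken. Muscle, fibrous repair, and tendon and synovium genes were higher and red cell genes lower in GMTT. The muscle share was 3.45% against 0.363% and the erythroid share 4.85% against 8.95%. Whether the makeup of the pieces taken gives the differences in this contrast was not tested. Actc1, an actin gene of striated muscle, rose from 0.783 ± 0.0478 to 47.0 ± 1.51 normalised CPM (log2 5.90, SE 0.11). Prg4, the joint lubricant lubricin, rose by 5.19 (SE 0.09), and Lyc2, Ip6k3 and Xirp1 by 4.77, 4.09 and 4.06. Fam111a fell by 3.42 (SE 0.08), and Lgals5 (-2.44), Adamts13 (-1.81), Selenbp1 (-1.58) and Cyb561a3 (-1.55) fell too. In all, 9218 genes were called, 4706 higher and 4512 lower, of which 1854 changed at least 2-fold, 1465 higher and 389 lower.

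Nlrp3 was 28.1 ± 2.80 CPM in GMTT and 19.5 ± 0.971 in Sham (log2 0.52, SE 0.08), Il1b 13.7 ± 0.618 and 8.05 ± 0.431 (0.77, SE 0.09), and Casp1 and Pycard differed by 0.24 and 0.25 (SE 0.07 each), the Casp1 call being lost on log2(FPKM + 0.1) and on unfiltered log2(FPKM + 1). Il18 was 0.55 higher (SE 0.19), a call lost without Sham replicate 1 (0.33), with DESeq2 and on the same FPKM scales. Gsdmd differed by 0.03 (adjusted p = 0.723 in edgeR's quasi-likelihood test) and by -0.0045 without GMTT replicate 1. Scaled to leukocyte genes, Nlrp3 (0.38) and Il1b (0.63) passed, Casp1, Pycard and Il18 did not (0.10, 0.10 and 0.40), and Gsdmd was -0.11. The inflammasome list had 11 higher and 2 lower of 17 and was not called by camera (adjusted p = 0.134) but was by fry (adjusted p = 0.00211, higher).

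Col2a1 was 2.39 ± 0.323 CPM in GMTT against 13.9 ± 0.955 in Sham (log2 -2.53, SE 0.12), while Acan was 0.69 higher (SE 0.08). Col10a1 (-0.39), Sox9 (-0.49) and Mmp13 (-0.06) were not called, Sox9 being called without Sham replicate 3 (-0.73). Hmox1 fell by 0.61 (SE 0.06) and Nqo1 rose by 0.88 (SE 0.11). The cartilage, hypertrophic, osteoblast and osteoclast lists were not called by camera (adjusted p 0.599 to 0.902). Fry called the hypertrophic list higher (adjusted p = 0.000645) and the osteoblast list lower (0.0177), but neither the cartilage list (0.322) nor the osteoclast list (0.133).

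All 22 fibrous repair genes rose, including Col3a1 from 449 ± 6.79 to 1882 ± 18.6 CPM (log2 2.07) and Postn (1.87), as did 10 of 10 tendon and synovium genes (Thbs4 1.72), 26 of 26 muscle genes (Myh4 3.69, Mybpc2 3.92), 15 of 18 adipocyte genes (Plin4 2.98, Lpl 1.55) and 16 of 20 hypoxia and glycolysis genes (Tpi1 1.59). All 23 proliferation genes fell (Ccnb2 and Ccna2 -0.64 each), as did all 19 erythroid genes (Ahsp -1.10, Rhd -1.02) and 16 of 19 B lymphocyte genes (Rag1 -1.12). These 8 calls held with an estimated correlation (adjusted p 0.00568 to 0.0339). Called at the preset correlation alone were matrix degradation with 16 of 19 higher, among them the stromelysin gene Mmp3 with 3061 counts against 1 in Sham (ratio 2897, counting interval 519.5 to 114500), inflammatory genes with 10 of 19 higher, including Nos2 (2.17), endothelial genes with 14 of 17, T and NK genes with 14 of 19, and the oxidative phosphorylation, mitochondrially encoded and ribosomal lists. Their adjusted p with an estimated correlation was 0.0695, 0.078, 0.078, 0.0653, 0.16, 0.255 and 0.291. In this contrast 21 of 23 oxidative phosphorylation genes rose (22 adjusted over the list alone), such as Ndufs1 (0.77) and Sdhb (0.68), 13 of 13 mitochondrially encoded genes rose, and 56 of 79 ribosomal protein genes fell. The other lists were not called by camera, among them neutrophil genes with 16 of 22 higher (17 adjusted over the list alone; adjusted p = 0.126, but 0.0335 and 0.0191 without GPI replicate 1 or 2). Adjusted over the list alone, 12 rather than 10 antioxidant genes and 6 rather than 4 monocyte genes were lower, and other counts were the same. Camera's direction differed from the median, the mean or both in the other cell death, cartilage, osteoclast, antioxidant and megakaryocyte lists, none of them called by camera.

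The design also asks how far the hydrogel group moved back from injury. Of the 14049 genes called in GPI against Sham, 12852 (91.5%) were called in the opposite direction in GMTT against GPI, 5954 higher in GPI and then lower, and 6898 lower and then higher, such as Abra, Xirp1, Np4, Slc14a1 and Mki67; 132 were called in the same direction. The split of 5954 and 6898 holds on the TMM scale. With library sizes only, 3016 genes were called lower in GMTT than in GPI, so no more than these could be higher and then lower. Against Sham, 8574 of the 14049 were still called in GMTT and 5475 were not. Both contrasts use the GPI libraries, which alone gave 0.15 opposite calls on average in 20 simulations of unchanged groups, and independent lists would share 2565 and 3503. Unchanged groups give almost no calls, so neither value shows what to expect when GPI differs from both other groups. GMTT and Sham libraries correlated at 0.955 to 0.957, and GPI with either at 0.614 to 0.716. Whatever set GPI apart, injury or the tissue taken, would therefore give many opposite calls. Across genes, which are not independent replicates, the fold changes correlated at -0.96 (simulated -0.64), with a covariance of -7.02 (simulated -0.0237). When GPI and Sham were compared without 1 GPI library and GMTT was set against that library, 96.9% to 97.1% of the genes called higher in GPI were lower and 96.3% to 96.6% of those called lower were higher in GMTT. GPI libraries correlated at 0.991 to 0.9915 with each other, so whatever set GPI apart would give high shares here too. If RNA was shared, the library left out is also not independent. Among the 9285 genes that differed at least 2-fold between GPI and Sham, the median difference between GMTT and Sham was 15.4% of that between GPI and Sham on the log2 scale. These counts include the muscle and marrow genes whose shares of the counts differed between the groups.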

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

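The fit without mitochondrially encoded, muscle and erythroid list genes and the scaling to leukocyte genes were chosen after the data were seen. The numbers of genes called in the 3 contrasts and called oppositely after GMTT stayed within 1.5 times under every alternative but a 2-fold minimum, which by its construction gave 9285, 8453, 1854 and 7962. Leaving out 1 library gave 13858 to 14269, 13441 to 13881, 8355 to 9282 and 12568 to 12920. Similar counts did not always mean the same directions. With library sizes only, 11183 of the 12998 calls shared with the main fit kept their sign in GPI against Sham. In GMTT against GPI 10301 of 12446 did, and in GMTT against Sham all 9076. With a replicate block the counts were 13960, 13574 and 8815 and no call of a named gene or list changed; same-numbered libraries did not deviate together (correlations -0.146 to 0.0614, 3 of 9 libraries closest to their own number). With library sizes only, the log2 fold change of Acan was -0.33 in GPI against Sham and 1.02 in GMTT against GPI, where Col2a1 was 0.46 and Nqo1 0.85; directions turned for the hypertrophic list (adjusted p = 0.812 and 0.904 in these contrasts), the antioxidant list (0.635 and 0.665) and, in GMTT against GPI, the fibrous repair list (0.509). Scaled to leukocyte genes, Nlrp3, Casp1, Pycard, Gsdmd, Il1b and Il18 were 0.20, 2.75, 1.38, 3.93, 1.10 and 3.30 in GPI against Sham, the last 5 were -2.66, -1.28, -4.04, -0.47 and -2.89 in GMTT against GPI, and Gsdmd was -0.11 in GMTT against Sham. By fry, the direction turned for matrix degradation and antioxidant genes in GPI against Sham (adjusted p = 1e-05 and 0.00396), antioxidant genes in GMTT against GPI (0.02) and other cell death in GMTT against Sham (0.133). The cause was not tested. An estimated correlation ended the call of 26 list tests over the 3 contrasts, while fry, which does not compare a list with other genes, called 30, 29 and 26 of 30 lists, 30 of these 85 tests not being called by camera and 27 of the 30 having camera's direction. Leaving out 1 library gave log2 fold changes of -0.0045 to 0.0844 for Gsdmd in GMTT against Sham and adjusted p of 0.911 to 0.995 for antioxidant genes in GPI against Sham and 0.796 to 0.982 for cartilage genes in GMTT against Sham, with turned directions in each. Without mitochondrially encoded, muscle and erythroid list genes the counts were 14077, 13714 and 9172. Depth limits Ihh, at 2 to 10 counts per group, and Sox9, at 57 to 105. It also limits the axis genes Il1b, Nlrp3, Il18 and Pycard in GPI, at 13, 17, 19 and 53 counts over the group.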

Other observations

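All tests of tissue makeup and the scaling to leukocyte genes were chosen after the result was seen; those on leukocyte medians, immunoglobulin genes and splits were set before their results were seen.

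GMTT went beyond both other groups on the TMM scale for 1365 genes that were higher and 813 that were lower than in Sham and in GPI, 240 and 40 of them at least 2-fold against each. These counts are given for no other scaling. With library sizes only, GMTT against GPI had 11503 genes higher and 3016 lower, so the balance of 1365 and 813 depends on the scale. Among genes with a proper symbol and a mean log2 CPM of at least 3, ordered by the smaller of the fold changes and named here after their values were seen, the first 6 higher ones were the lysozyme gene Lyc2 (200.1 ± 22 normalised CPM in GMTT, 1.90 ± 0.152 in GPI and 7.33 ± 0.209 in Sham, SD, n = 3), the MHC class II gene RT1-Da (99.9, 19.7 and 27.3), Oas1k (24.6, 6.93 and 7.26), the mast cell protease Mcpt10 (274, 0.0282 and 114), the matrix proteoglycan Vcan (143, 60.1 and 42.0) and the class II invariant chain Cd74 (342, 45.3 and 145). By list, 16 of 22 neutrophil, 12 of 19 T and NK, 11 of 19 monocyte and 10 of 19 matrix degradation genes were higher than in both, as were 9 of 17 inflammasome genes. Against GPI alone, 22 of 22 neutrophil, 17 of 19 T and NK and 18 of 19 monocyte genes were higher, so their counts rest mainly on the difference from Sham. There camera did not call the neutrophil, monocyte and inflammasome lists (adjusted p = 0.126, 0.258 and 0.134). It called the T and NK and matrix degradation lists at the preset correlation alone.

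Interferon genes, also named after their values were seen, parted in GMTT on the TMM scale, with 3 of 17 higher and 8 of 17 lower than in both groups. With library sizes only, the median of all genes in GMTT against GPI moved from 0.12 to 1.22 (log2), so small differences from GPI could turn. Camera did not call this list against GPI or Sham (adjusted p = 0.289 and 0.272). Fry called it lower in both contrasts (adjusted p = 4.59e-07 and 0.00703). Ifit1 was 67.8 ± 3.03 CPM against 30.7 in GPI and 17.0 in Sham, and Gbp2 53.7 ± 1.27 against 21.7 and 25.8. Irf7, a transcription factor of this response, was 16.2 against 56.6 and 35.9, and Herc6, outside the list, 6.35 ± 0.767 against 42.2 and 13.2.

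The higher muscle and lower marrow genes of GPI were weighed against 4 explanations. Muscle added to an otherwise unchanged femur would lower the femur's own lists by 1 factor, but the medians of the erythroid, neutrophil, B lymphocyte, osteoblast and cartilage lists spanned 10.18 (log2, bootstrap SD 0.484), and library scaling would not leave the smallest of the 5 muscle and marrow medians at 5.22 with library sizes only. Marrow lost from an otherwise unchanged femur would raise the other lists by 1 factor, but the medians of the muscle, osteoblast and cartilage lists spanned 7.65 (bootstrap SD 0.376). The prediction for added muscle assumes that the added tissue expresses none of the femur list genes. That for lost marrow assumes that marrow expresses none of the muscle, osteoblast and cartilage list genes. Neither assumption was checked, so the spans cannot exclude these explanations. A different tissue makeup of the pieces taken needs the muscle, erythroid, neutrophil, B lymphocyte and megakaryocyte lists to move as wholes, and 98 of 99 tested members (98.99%) did. Tfrc (0.22), named after its value was seen, was the exception. This was tested on lists that showed the pattern, so it is a hypothesis, and a response to injury that changes muscle and marrow together and a mix-up of tissues or groups before sequencing stay open, as untested.

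The lower axis genes of GPI may reflect fewer leukocytes. The median of the 6 axis genes lay 1.91 ± 0.86 (bootstrap SD) above that of 16 leukocyte genes in GPI against Sham, 1.90 below it (a difference of -1.90 ± 0.91) in GMTT against GPI, and 0.25 ± 0.14 above it in GMTT against Sham. The bootstrap drew genes again and not libraries, so its SD measures the spread between genes and not between rats. Leukocyte number alone was taken to need a difference within 1 in the contrasts with GPI. Exclusion needed a difference above 2 by more than 2 bootstrap SD, and the values lay between these limits. Against Sham the value of 0.2518 lay above the limit of 0.25 by less than its spread. Exclusion there also needed a leukocyte median below 0.1, which was 0.133. Leukocyte number and regulation of the axis therefore cannot be told apart here. Scaled to leukocyte genes in GMTT against Sham, the calls of the axis genes split. Nlrp3 (0.38, adjusted p = 0.000242) and Il1b (0.63, adjusted p = 2e-06) stayed called in edgeR's quasi-likelihood test. Casp1, Pycard and Il18 (0.10, 0.10 and 0.40) and Gsdmd (-0.11) were not called (adjusted p 0.0717 to 0.257, same test). This scaling takes no account of differences between types of leukocyte. In this contrast the list medians were 0.32 for neutrophil, 0.23 for monocyte, 1.08 for T and NK and -0.59 for B lymphocyte genes (log2). The calls of Nlrp3 and Il1b therefore cannot tell regulation from a different mix of leukocytes. Il18 had a larger fold change than Nlrp3 but also a larger SE (0.19 against 0.08), and no test compared the axis genes with each other. An effect of injury or hydrogel on the axis within cells stays open, as untested.

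Libraries of a group differed little, with a median biological coefficient of variation of 5.09%, and the muscle share, looked at after its values were seen, varied by 3.10%, 0.908% and 3.51% of its mean in Sham, GPI and GMTT. Pooled tissue or shared RNA is a possible explanation. The test set beforehand, the variation of immunoglobulin V genes between animals, was void: 1 such gene had a mean of at least 50 counts in both groups, and its estimate was 0. Shared RNA and animals that differ little cannot be told apart from these counts.

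Other splits of the libraries bear on the counts of calls. For each contrast, 1 of the 10 splits of its 6 libraries, the real one, gave as many calls (14049, 13685 and 9218), the highest other split gave 0 by edgeR, with at most 44, 68 and 713 genes at an unadjusted p below 0.05, and 10 splits are too few for a share under 0.05. For genes called oppositely after GMTT, 1 of 100 splits into 3 groups, the real one, gave as many as the real 12852, a share under 0.05. This bears on whether the groups differ and not on the reversal itself. A split that mixes libraries of unlike groups widens the spread within its groups and so gives few calls. The comparison therefore adds no support for the reversal. The highest other, 7004, kept the 3 groups whole and put Sham in the middle, the next gave 57 with GPI and GMTT libraries mixed, and 97 gave 0.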
